A study of Mus musculus with 9 samples.

How the data were processed

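RNA abundance was measured on 9 Agilent long-oligonucleotide mouse arrays of design 014868. Per the labels' protocols, cells were taken from prostates of BL6 mice, stained with fluorescent antibodies and separated by FACS (fluorescence-activated cell sorting). Total RNA was isolated with a PicoPure kit, amplified with a MessageAmp II kit and labelled with a Quick Amp kit. The sample RNA carried Cy5 and a common reference, pooled mouse RNA from Stratagene, carried Cy3 on every array, so no dye swap was available.

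The scanner files hold spot intensity values for both channels, written by Agilent Feature Extraction 10.7 per the submitters' processing notes, and version 10.7.3.1 per the file headers. Each file holds mean and local background intensity values per spot, not yet normalized, together with processed intensity values that the scanner software had background-subtracted and dye-normalized, per the file headers. A log10 ratio of Cy5 over Cy3 is also listed per the file headers, and was not used here. The authors' deposited table gives a log2 difference and mean, a p-value and adjusted p-value, limma's score columns and a signed fold for stem over non-stem cells. How those values were normalized is not given in the sources used here.

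Mean intensities were corrected with limma 3.58.1 in R 4.3.3 by normexp, with the median local background and an offset of 50. Ratios were normalized by loess within each array, with control and outlier spots at weight 0 and no scaling between arrays. Outlier spots were set to missing, and spots of a probe were averaged. Of 41174 probes, 28332 were well above background in Cy5 on at least 3 arrays and were tested. Probes were named through RefSeq accessions and symbols of the GRCm38.p6 gene table, of which no coordinates were used: 22951 by the systematic name, 119 by the accession column, 6585 by a current symbol and 3077 by a synonym, while 8442 kept the name in the file. The tested probes stood for 19849 genes or transcripts, 16118 of them with a current symbol. A gene was represented by its tested probe with the highest mean intensity over both channels. Coordinates are those of probes in the scanner files, whose header names build mm7:NCBI35:Aug2005. Exons and untranslated regions of that build were not used here.

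The marker-positive group (3 arrays) was compared with the marker-negative group (6 arrays) by limma's moderated test with trend and robust variance estimation, two-sided. Adjusted p-values are Benjamini-Hochberg values over all tested probes, with a threshold of 0.05. A difference is the mean log2 ratio of marker-positive minus that of marker-negative arrays, and SE is its moderated standard error. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 30 lists, after missing values were replaced by group means. Those lists, 14 of cell type markers and 16 of processes, held 402 genes. Camera with an estimated correlation and fry were alternatives. Fry's directional p asks whether a list's genes move one way on balance, its mixed p whether they change in either direction, and neither compares the list with other genes.

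The gene lists, the tests of genes and lists and the rule for named genes were fixed before the data were examined, and tests of explanations chosen later are named as such. The rule took the 12 largest positive and 12 largest negative differences among called genes whose groups did not overlap, the 4 sort markers, up to 4 members of each list with the smallest adjusted p, and every measured member of lists with 5 or fewer. A gene not well above background on any array of a group is named as such, and its log2 difference is then set against background.

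The files place the arrays on 5 slides, and slides 1 and 2 held both groups. Slide 1 carried marker-positive replicate 1 and marker-negative replicate 1. Slide 2 carried marker-positive replicate 2 and marker-negative replicates 2 and 4. Slide 3 carried marker-negative replicates 3 and 6, and the remaining slides carried 1 array each. Replicate numbers follow the order of deposit and pair nothing.

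Alternatives covered the background correction, normalization, detection filter, variance model, array weights, slide as a block, each array left out, a tested fold minimum, the probe rule and the set test. An analysis of slides 1 and 2 alone and a model with Cy5 detection as a covariate were chosen after seeing the data. The deposited table holds no values per array, so it could not replace the scanner files. The procedure was tested on simulated data for 3 against 6 arrays and 28332 probes with 200 changed genes. It recovered 44% of 100 genes changed by log2 2 and 16% of 100 changed by log2 1, all with the right sign. Of its 64 calls 6.25% were false. The simulated noise was independent for each probe and array, with no slide effect and no correlation between genes, so these rates may not carry over. Plots were drawn with matplotlib 3.10.9.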

Results

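The series compared 2 fractions of primary mouse prostate cells to ask how gene expression differs between them. Marker-positive cells, called stem cells in the labels, were negative for lineage markers and positive for CD44, CD133, Sca-1 and CD117. Marker-negative cells lacked lineage markers and all 4 of these surface proteins. There were 3 marker-positive and 6 marker-negative arrays. Cy5 signal was well above background for 67.3%, 69.3% and 45.5% of probes on marker-positive replicates 1 to 3. On the marker-negative arrays that share ran from 47.5% to 69.5%, and its group means were 60.7% ± 13.2 (SD, n = 3) and 59.4% ± 7.71 (SD, n = 6). Across probes, log2 ratios of marker-positive replicates 1 and 2 correlated at 0.923, while replicate 3 reached 0.609 and 0.582 with them. Marker-negative pairs lay between 0.668 and 0.901. Pairs between the groups lay between 0.483 and 0.729. Marker-positive replicate 3 correlated more with marker-negative replicates 4 (0.677) and 6 (0.676) than with its own group. The files do not show whether marker-positive replicates 1 and 2 came from separate samples, and they were counted separately as the labels list them. The labels do not say that arrays of a group came from separate animals, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

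Transcripts of 3 of the 4 sort markers were higher in marker-positive cells, which is a check of the labels since the cells were chosen by these proteins. The check does not show which cells carried the transcripts. Among marker-negative arrays Kit was highest on replicate 3 (3.34), as was the mean of the mast cell list (2.97). Among marker-positive arrays Ly6a was lowest on replicate 3 (0.53), as was the mean of the fibroblast list (-2.86). Ly6a, which encodes Sca-1 (probe on chromosome 15, 75075673 to 75075732, build mm7), had a mean log2 ratio to the reference of 1.96 ± 1.26 (SD, n = 3) against -1.97 ± 0.94 (SD, n = 6). That difference was 3.93 (SE 0.65, limma adjusted p = 0.0132). Kit, which encodes CD117, was higher by 3.45 (SE 0.78, adjusted p = 0.0460). Cd44 was higher by 2.06 (SE 0.36, adjusted p = 0.0166). Prom1, which encodes CD133 (probe on chromosome 5, 43314657 to 43314716), did not pass. Its log2 ratio was 1.83 ± 1.44 (SD, n = 3) against 2.27 ± 0.83 (SD, n = 6), a difference of -0.44 (SE 0.64, adjusted p = 0.766). A second Prom1 probe, not well above background on any marker-positive array, gave -0.90 (adjusted p = 0.223). Other Cd44 probes gave 1.64 (adjusted p = 0.0804) and -0.00 (adjusted p = 0.995). Within slides 1 and 2 the differences were 5.10 and 5.40 for Ly6a, 3.95 and 2.53 for Kit, 2.20 and 1.77 for Cd44, and -0.06 and 0.08 for Prom1. Ly6a alone passed when slide was a fixed block (5.27), while Kit (3.14) and Cd44 (1.96) did not. Median centring (2.59) and the mean of its probes (1.23) ended the Cd44 call. The Kit call ended with processed signals (3.75), no background subtraction (3.48), an offset of 16 (3.75), Cy5 alone (2.80) and no detection filter (3.45). It also ended without any array except marker-negative replicate 3 (2.59 to 4.08). The Ly6a call ended without marker-positive replicate 1 (3.68) or 2 (3.46), and the Cd44 call without marker-positive replicate 1 (1.88).

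**Figure D1:**
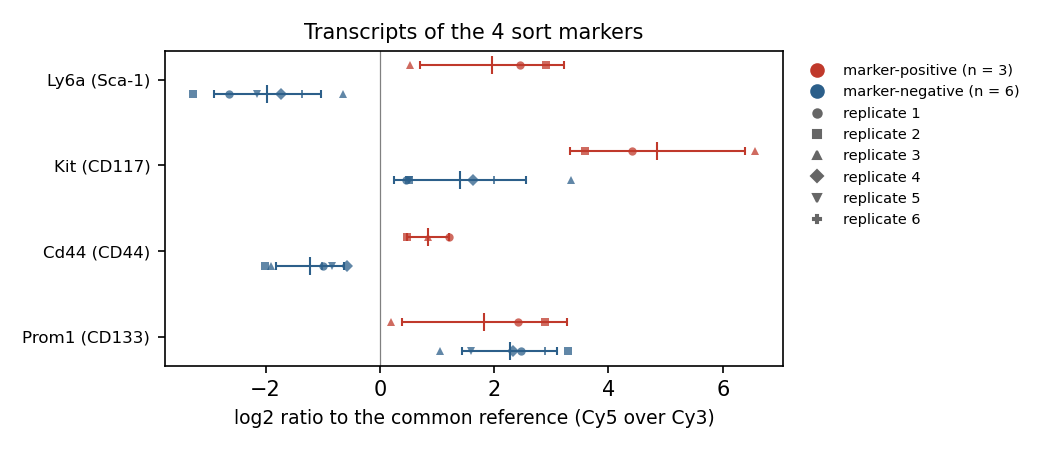
Log2 ratio of Cy5 sample to Cy3 reference (horizontal axis) for the transcripts of the 4 sort markers, with a point per array, red for marker-positive (n = 3) and blue for marker-negative (n = 6), symbols for replicates, and bars for the mean ± SD. The groups do not overlap for Ly6a, Kit and Cd44 and overlap for Prom1, whose means were 1.83 and 2.27.

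Over all genes, 312 were higher and 331 lower in marker-positive cells at an adjusted p under 0.05 (limma), of which 298 and 320 differed by at least 2-fold. In 639 of these 643 genes the groups did not overlap, against 2305 of all 19849 genes (11.6%) and 2.38% by chance. The test favours genes whose groups lie apart, so the lack of overlap among called genes adds no support. A fixed block for slide left 125 higher and 20 lower, with 62 of the 643 genes called the same way. Median centring in place of loess gave 141 higher and 85 lower. Without marker-positive replicates 1, 2 and 3 the higher counts were 98, 114 and 933 and the lower counts 90, 87 and 498. Without marker-negative replicates 1, 2 and 5 they were 160, 185 and 185 higher and 150, 186 and 169 lower, and 200 were higher without replicate 6.

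The 12 largest positive differences included Mrc1 from the macrophage list and Cpa3 from the mast cell list, and the other 10 genes were in no list. F13a1, the A chain of coagulation factor XIII (probe on chromosome 13, 36288206 to 36288265), had log2 ratios of 6.96 ± 0.83 (SD, n = 3) against -1.04 ± 1.01 (SD, n = 6). This was a difference of 8.004 (SE 0.62, adjusted p = 0.000398) or 257-fold. The macrophage receptors Cd163 (chromosome 6, 124312766 to 124312825) and Mrc1 (chromosome 2, 14281098 to 14281158) were not well above background on any marker-negative array. Against that background, Cd163 was higher in marker-positive cells by 5.93 (SE 0.24, adjusted p = 9.85e-06) and Mrc1 by 6.01 (SE 0.38, adjusted p = 0.000118). The chemokines Ccl24 and Ccl8 were higher by 6.57 (SE 0.54, adjusted p = 0.000549) and 6.10 (SE 0.38, adjusted p = 0.000118). The eosinophil-associated ribonucleases Ear1 and Rnase2a were higher by 6.58 (SE 0.90) and 5.81 (SE 0.74), though their probes may share signal between near-identical copies of the family. Clec10a, a lectin of macrophages and dendritic cells, was higher by 5.94, the chemokine Pf4 by 5.92, the ficolin Fcna by 5.89, the gelatinase Mmp9 by 5.84 and the mast cell carboxypeptidase Cpa3 by 5.73 (SE 1.15, adjusted p = 0.0289). Of the 6 marker-negative arrays, Mmp9 was well above background on 1, Ear1 and Ccl24 on 2, and Fcna, Ccl8 and Cpa3 on 3. The differences of these genes therefore rest partly on background. When slide was a fixed block, F13a1 (8.74), Ccl24 (7.22), Ccl8 (5.84), Mrc1 (5.98), Cd163 (5.64), Fcna (6.39) and Mmp9 (6.74) passed. Ear1 (5.57), Rnase2a (4.95), Clec10a (5.90), Pf4 (6.18) and Cpa3 (5.91) did not. Processed signals ended the calls of Ear1 (6.70), Clec10a (6.09) and Cpa3 (6.95). Only the Cpa3 call ended when an array was left out, for any marker-positive array and marker-negative replicates 1, 2, 5 and 6 (5.25 to 6.19).

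The 12 largest negative differences included Cd3d and Cd3g from the lymphocyte list and Msmb from the secretory list, and the other 9 genes were in no list. Gzma, a granzyme (serine protease of cytotoxic granules; probe on chromosome 13, 110251676 to 110251735), had log2 ratios of 0.39 ± 0.94 (SD, n = 3) against 7.04 ± 1.63 (SD, n = 6). The difference was -6.65 (SE 0.91, adjusted p = 0.00567). Gzmc was not well above background on any marker-positive array and differed by -6.64 (SE 0.82, adjusted p = 0.00357), a value set against background. Gzmb differed by -5.12 (SE 0.28, adjusted p = 7.29e-05), with 0.75 ± 0.09 (SD, n = 3) against 5.87 ± 0.34 (SD, n = 6). Cd3d and Cd3g, subunits of the T cell receptor complex, differed by -5.27 and -4.81, and the transcription factor Tbx21 by -4.87. The death ligand Fasl differed by -4.82 and the protease Ctsw by -4.56. Msmb, a secreted protein of the prostate, fell from 8.34 ± 0.75 (SD, n = 6) in marker-negative to 3.101 ± 1.71 (SD, n = 3) in marker-positive cells (-5.24, SE 0.70, adjusted p = 0.00531). The apolipoprotein Apof differed by -4.55, the linker histone H1f4 by -4.53 and the splicing factor Srsf5 by -4.74, although a second Srsf5 probe gave 0.24 (adjusted p = 0.861). Of the 3 marker-positive arrays, Gzma was well above background on 1 and Cd3d, Fasl, Ctsw and Apof on 2. The differences of these genes therefore rest partly on background. Gzmb (-4.91) passed when slide was a fixed block and the other 11 did not. Their differences were then -7.09 for Gzma, -6.30 for Gzmc, -5.57 for Cd3d, -5.27 for Cd3g and -4.42 for Tbx21. They were -4.46 for Fasl, -3.92 for Ctsw, -3.62 for Msmb, -3.56 for Apof, -3.98 for H1f4 and -3.76 for Srsf5. Median centring ended the calls of Tbx21 (-4.20), Cd3g (-4.68) and Apof (-3.61), processed signals that of Apof (-3.98), and the mean of a gene's probes that of Srsf5 (-2.25). Calls ended for Cd3d without marker-positive replicate 1 (-4.96) or 2 (-4.71), and for Fasl without marker-positive replicate 1 (-4.83). The Cd3g call ended without marker-positive replicates 1 and 2 or marker-negative replicates 1, 5 and 6 (-4.87 to -4.34).

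**Figure D2:**
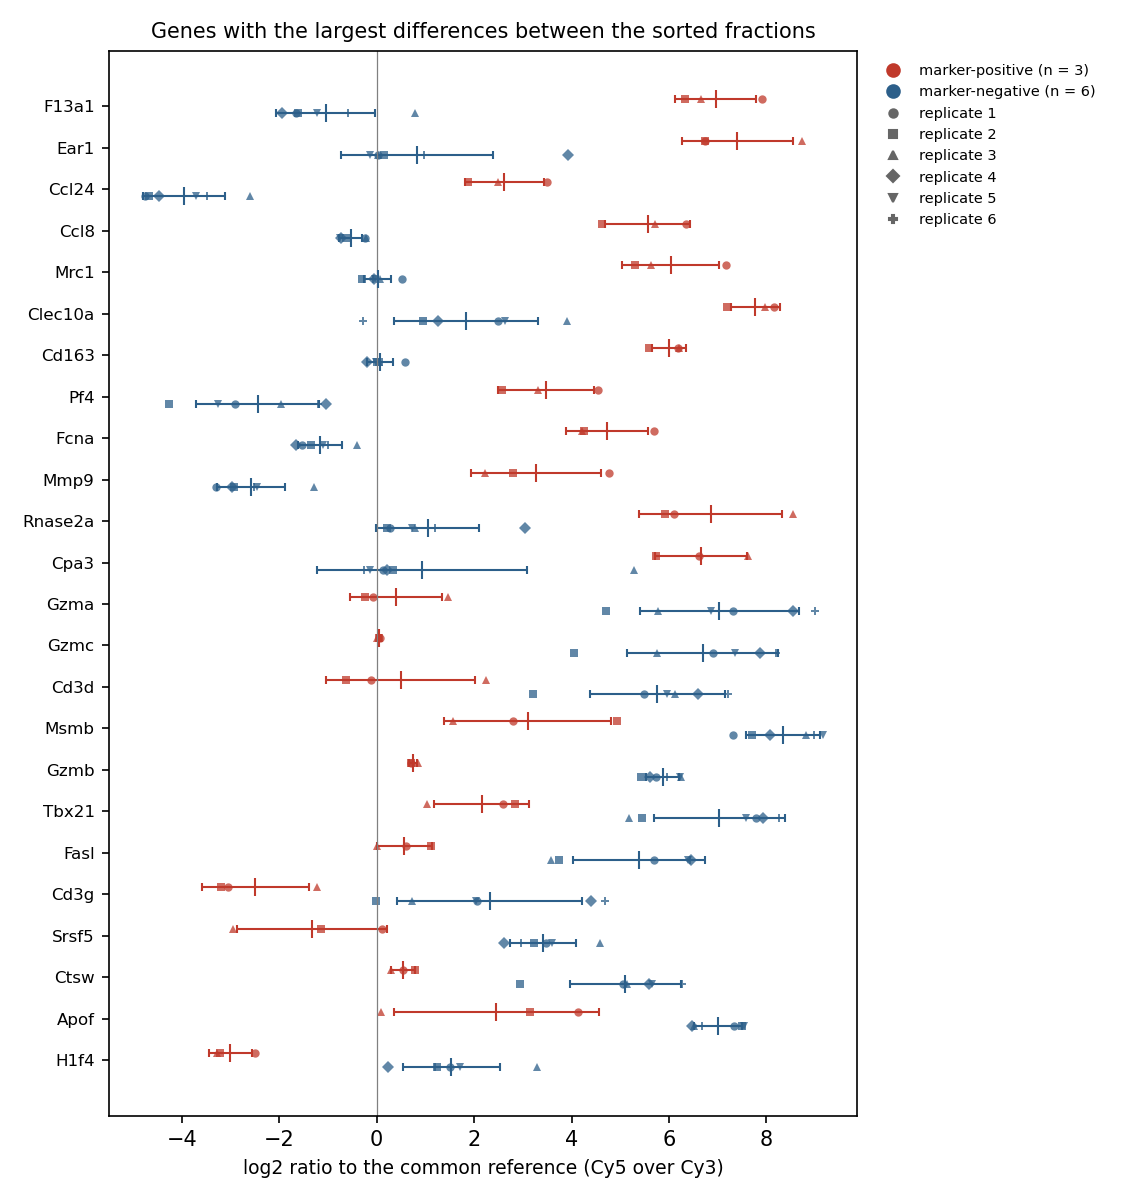
Log2 ratio of Cy5 sample to Cy3 reference (horizontal axis) for the 12 genes with the largest positive and the 12 with the largest negative differences, with a point per array, red for marker-positive (n = 3) and blue for marker-negative (n = 6), symbols for replicates, and bars for the mean ± SD. The groups do not overlap for any of these genes, which were chosen for that, and marker-negative replicate 3 lies at 5.29 for Cpa3.

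Some secretory prostate genes were lower in marker-positive cells. Of 15 measured secretory and androgen-responsive genes 4 were lower and none higher: Msmb, the androgen-regulated Pbsn (-1.99, SE 0.43), the protease Tmprss2 (-2.28, SE 0.39) and Azgp1 (-2.27, SE 0.29). Adjusted over the list alone, 8 were lower and 1 higher. The list median was -1.44 (camera adjusted p = 0.0212, but adjusted p = 0.414 with an estimated correlation). Among 15 luminal epithelial genes, which include Prom1, Ehf was lower (-2.34, SE 0.40) and 14 did not pass, with 5 lower adjusted over the list alone. All 15 had negative differences, with a median of -1.03 (adjusted p = 0.000611, but adjusted p = 0.414 with an estimated correlation). Of 14 basal epithelial genes Trp63, the basal transcription factor p63, was higher (2.02, SE 0.45, adjusted p = 0.0446), with 2 higher adjusted over the list alone. The basal median was 0.83 (adjusted p = 0.00651, but adjusted p = 0.414 with an estimated correlation). None of 11 proximal duct and urethral genes passed, over all genes or adjusted over the list alone. Their median was 0.76 (adjusted p = 0.0305, but adjusted p = 0.414 with an estimated correlation). The block for slide gave medians of -1.22 for secretory genes, no longer called, -0.67 for luminal, 1.78 for basal and 2.36 for duct genes. Within slides 1 and 2 they were -1.46 and -1.09 (secretory), -0.97 and -0.57 (luminal), 1.02 and 2.06 (basal), and 2.04 and 2.03 (duct). Without marker-positive replicate 3 the secretory (-1.11) and luminal (-0.59) calls ended and the basal and duct medians were 1.53 and 1.78. The basal call ended without marker-positive replicate 2 (0.47), and the duct call without marker-positive replicates 1 (0.55) and 2 (0.41) or marker-negative replicate 3 (0.82). Median centring ended the calls of Azgp1 (-2.20), Tmprss2 (-2.11), Pbsn (-2.04) and Trp63 (1.83). Processed signals ended those of Pbsn (-0.61), Trp63 (3.30), the secretory list (-0.66) and the duct list (0.84), and gave a luminal median of -1.76. Detection in both channels on all arrays ended the calls of the secretory (-1.08), basal (0.62) and duct (1.17) lists. Array weights ended the secretory call (-1.40) and gave medians of 1.32 for basal and 1.94 for duct genes. An offset of 16 ended the Pbsn call (-1.55), and no detection filter ended those of Pbsn and Trp63. Single-gene calls ended for Trp63 without any array except marker-positive replicate 3 (1.49 to 2.14) and for Ehf without marker-positive replicate 2 (-2.49). They ended for Tmprss2 without marker-positive replicate 1 (-2.04) or 2 (-2.20), and for Pbsn without marker-positive replicate 2 or any marker-negative replicate but 4 (-2.20 to -1.88).

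Of the endothelial genes 2 were higher in marker-positive cells. Vwf, the von Willebrand factor, was higher by 3.99 (SE 0.60, adjusted p = 0.00843) and Ly6c1 by 3.63 (SE 0.67, adjusted p = 0.0218) among 15 measured, with 5 higher adjusted over the list alone. The endothelial median was 2.19 (camera adjusted p = 2.1e-05, but adjusted p = 0.414 with an estimated correlation). None of 14 fibroblast genes passed over all genes, and 5 were higher adjusted over the list alone. All 14 differences were positive, with Fbn1 at 3.11 (SE 0.82, adjusted p = 0.0747). Their median was 1.78 (adjusted p = 0.000316, but adjusted p = 0.414 with an estimated correlation). None of 12 smooth muscle and pericyte genes passed over all genes or adjusted over the list alone, with a median of 0.70 (adjusted p = 0.00620, but adjusted p = 0.414 with an estimated correlation). The mean log2 ratio of the fibroblast list was 1.23 and 1.12 on marker-positive replicates 1 and 2 and -2.86 on replicate 3. That of the endothelial list was 3.27, 4.70 and 0.51. On marker-negative arrays the fibroblast mean ran from -3.05 to -0.64 and the endothelial mean from 0.34 to 1.78. Marker-positive replicate 3 lay within both ranges, so the higher values rest on marker-positive replicates 1 and 2. Without replicate 3 the medians were 3.49 (endothelium), 3.53 (fibroblasts) and 1.14 (smooth muscle). They were 3.39, 3.42 and 1.34 with a block for slide, and the fibroblast median was 3.02 with array weights. Within slides 1 and 2 the medians were 1.27 and 4.58, 2.47 and 4.17, and 0.21 and 2.10. Marker-positive replicate 3 was alone on slide 5 and so adds nothing to the block and within-slide values. Its array weight was 0.240, so these settings mostly repeat the fit without it. Without marker-positive replicate 2 the endothelial median was 1.10 and the smooth muscle call ended (0.33), and without replicate 1 the fibroblast median was 1.12. With slide as a fixed block Ly6c1 (5.07) passed and Vwf (3.88) did not. The Ly6c1 call ended without marker-positive replicate 1 (3.48) or 2 (3.04) or marker-negative replicate 1 (3.52).

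Among blood cell genes, some of mast cells and macrophages were higher and some of lymphocytes and erythroid cells lower in marker-positive cells. Of 9 mast cell genes Cpa3, the tryptase Tpsb2 (2.45, SE 0.29, adjusted p = 0.00268) and the IgE receptor subunit Fcer1a (3.81, SE 0.46, adjusted p = 0.00342) were higher, with 6 higher adjusted over the list alone. The mast cell median was 2.49 (camera adjusted p = 2.1e-05, but adjusted p = 0.306 with an estimated correlation). Of 12 macrophage genes Mrc1, the lysozyme Lyz2 (4.88, SE 0.90) and the integrin Itgam (1.02, SE 0.19) were higher, 3 also adjusted over the list alone. The complement genes C1qa (0.47) and C1qc (0.16) and the adaptor Tyrobp (0.30) did not pass. The macrophage median was 1.02 (adjusted p = 0.000398, but adjusted p = 0.414 with an estimated correlation). Of 12 lymphocyte genes 4 were lower, Cd3d, Cd3g, the co-receptor Cd8a (-3.75, SE 0.64) and the NK cell receptor Klrb1c (-4.09, SE 0.81), with 7 lower adjusted over the list alone. The Cd8a probe was not well above background on any marker-positive array, so its value is set against background. The T cell genes Cd3e (-0.12) and Cd2 (0.41) did not pass. The lymphocyte median was -1.67 (adjusted p = 0.000398, but adjusted p = 0.414 with an estimated correlation). Of 3 measured erythroid genes the globin Hba-a1 (-3.34, SE 0.43, adjusted p = 0.00447) and the haem synthesis enzyme Alas2 (-4.04, SE 0.51, adjusted p = 0.00419) were lower, 2 also adjusted over the list alone, and Slc4a1 did not pass (-0.50). The erythroid median was -3.34 (adjusted p = 0.00284, but adjusted p = 0.414 with an estimated correlation). None of 10 genes shared by all leukocytes passed, over all genes or adjusted over the list alone, and their median was 0.58 (adjusted p = 0.0786). A block for slide gave medians of 3.47 for mast cells, 1.42 for macrophages, -1.71 for lymphocytes and -2.98 for erythroid cells. Within slides 1 and 2 they were 3.76 and 3.02, 2.08 and 1.003, -1.93 and -1.59, and -3.02 and -2.87. Detection in both channels on all arrays ended the lymphocyte (-0.42) and erythroid (-1.92) calls and left Cd8a to another probe, which did not pass (-2.27). The erythroid median was -0.26 without a detection filter and -5.48 with Cy5 alone, both still called. Processed signals (1.91), median centring (0.80) and Cy5 alone (1.19) ended the Itgam call. The Lyz2 call ended without marker-positive replicate 1 (4.81) or 2 (5.25), and so did that of Cd8a (-3.67 and -3.69). The Klrb1c call ended without marker-positive replicate 1 or 2 (both -4.11) or marker-negative replicate 1 (-4.19) or 5 (-4.14). The Itgam call ended without marker-positive replicate 1 (0.92) or marker-negative replicate 1 (1.01).

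**Figure D3:**
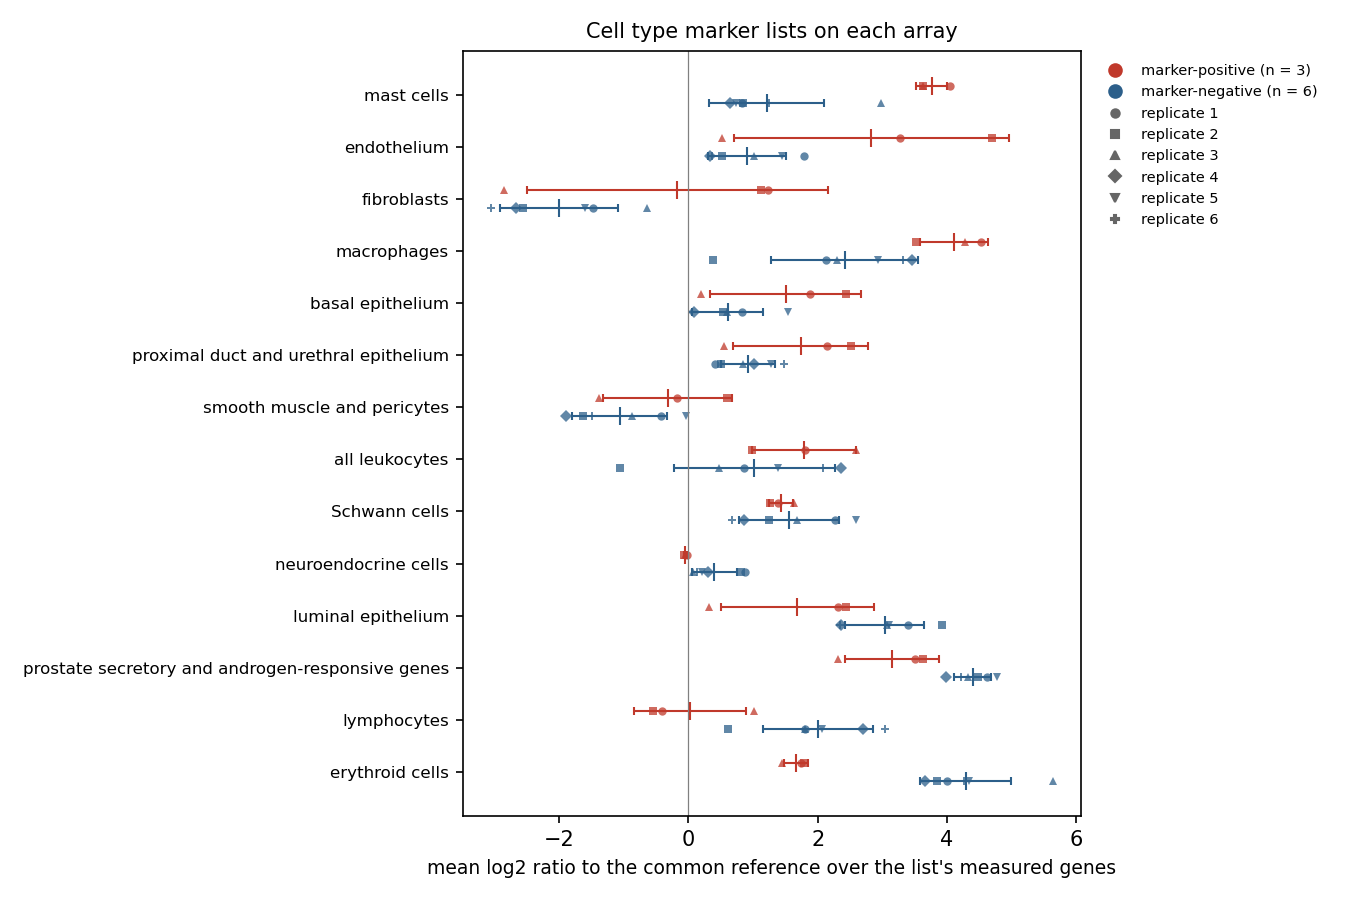
Mean log2 ratio to the Cy3 reference over the measured genes of each cell type list (horizontal axis), with a point per array, red for marker-positive (n = 3) and blue for marker-negative (n = 6), symbols for replicates, and bars for the mean ± SD. Marker-positive replicate 3 lies at -2.86 for fibroblasts against 1.23 and 1.12 for replicates 1 and 2, and the erythroid list separates the groups on every array.

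Of the interferon-responsive genes 2 were higher in marker-positive cells. Oasl2 was higher by 2.82 (SE 0.35, adjusted p = 0.00342) and Usp18 by 1.70 (SE 0.31, adjusted p = 0.0205) among 12, with 7 higher adjusted over the list alone and all 12 differences positive. The median was 1.67 (camera adjusted p = 1.4e-05, but adjusted p = 0.306 with an estimated correlation). Of 13 Notch pathway genes the receptor Notch4 (2.65, SE 0.58) and the ligand Jag1 (2.44, SE 0.50) were higher, with 3 higher and 1 lower adjusted over the list alone. Differences in this list ran from -1.65 to 2.65. Hes1, a member of the list, had a signed fold of -3.14 in the authors' deposited table (adjusted p = 0.0303). Activity of the pathway was not tested. The Notch median was 1.23 (adjusted p = 0.00337, but adjusted p = 0.414 with an estimated correlation). Of 11 mesenchymal transition genes the filament protein Vim was higher (2.78, SE 0.43) and the cadherin Cdh11 lower (-2.14, SE 0.27), although the mean of the Cdh11 probes gave -0.04. Adjusted over the list alone 6 of these were higher and 1 lower, with a median of 1.61 (adjusted p = 0.00327, but adjusted p = 0.414 with an estimated correlation). On marker-positive replicates 1 to 3 the mean log2 ratio of the Notch list was 0.98, 2.02 and 0.15, and that of the mesenchymal list -0.32, -0.17 and -1.54, each lowest on replicate 3 as were the endothelial and fibroblast lists. The Usp18 call ended without marker-positive replicate 1 (1.63) or 2 (1.66), and the Vim call without marker-positive replicate 1 (2.54). The Jag1 call ended without marker-positive replicate 1 (2.50) or 2 (2.44) or marker-negative replicate 1 (2.54) or 6 (2.41). The Notch4 call ended without any array but marker-positive replicate 1 and marker-negative replicate 4 (2.14 to 2.79). Without marker-positive replicate 2 the Notch call ended (0.49) and the mesenchymal median was 0.94. Median centring ended the calls of Notch4 (2.32), Cdh11 (-2.05) and Usp18 (2.07). Processed signals (3.83) and no detection filter (2.65) ended the Notch4 call, and detection in both channels on all arrays the Notch list call (0.77). A block for slide gave medians of 2.09 (interferon), 1.66 (Notch) and 2.65 (mesenchymal), and within slides 1 and 2 they were 1.70 and 2.42, 1.24 and 2.93, and 1.43 and 3.14.

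The chemokine Ccl7 was higher by 4.43 (SE 0.77, adjusted p = 0.0166) among 13 cytokine genes, with 3 higher adjusted over the list alone. The cytokine median was 0.93 (camera adjusted p = 0.0212, but adjusted p = 0.414 with an estimated correlation). Ier3 was higher by 2.81 (SE 0.56, adjusted p = 0.0287) among 13 immediate-early genes, which respond to cell dissociation, with 2 higher adjusted over the list alone. Their median was 0.39 (adjusted p = 0.0319, but adjusted p = 0.414 with an estimated correlation). None of 12 antigen presentation genes (median 0.93, adjusted p = 0.0238) and 14 basement membrane genes (median 1.31, adjusted p = 0.0194) passed, over all genes or adjusted over the list alone, and both lists had adjusted p = 0.414 with an estimated correlation. Of 15 endoplasmic reticulum and secretion genes none passed over all genes and 4 were lower adjusted over the list alone. Their median was -0.90 (adjusted p = 0.000373, but adjusted p = 0.414 with an estimated correlation). A block for slide ended the antigen presentation call (0.72). It gave medians of 2.24 for cytokine, 0.43 for immediate-early, 2.15 for basement membrane and -1.04 for secretion genes. Within slides 1 and 2 the medians were 2.47 and 2.30 (cytokine), -0.08 and 0.69 (immediate-early), 1.26 and 2.82 (basement membrane), -1.07 and -0.95 (secretion), and 0.68 and 0.59 (antigen presentation). The cytokine call ended without marker-positive replicate 1 (0.68) or 2 (0.62) or marker-negative replicate 2 (0.66), and its median was 2.27 without marker-positive replicate 3. The immediate-early call ended without marker-positive replicate 1 (0.30) or 2 (0.09) or marker-negative replicate 3 (0.40) or 6 (0.14). Its median was 0.97 without marker-positive replicate 3 and 0.60 without marker-negative replicate 1. The basement membrane call ended without marker-positive replicate 1 (0.76) or 2 (0.70), and its median was 2.12 without replicate 3. The antigen presentation call ended without marker-positive replicate 3 (0.55) or marker-negative replicate 2 (0.67). The immediate-early median was 0.60 with median centring, 0.71 with Cy5 alone and 0.66 with array weights, and Cy5 detection as a covariate, chosen after seeing the data, ended its call (0.29). Array weights gave a cytokine median of 2.20, and detection in both channels on all arrays a basement membrane median of 0.84. Median centring ended the Ier3 call (3.34). The Ccl7 call ended without marker-positive replicate 1 (3.42) or 2 (4.62). The Ier3 call ended without marker-positive replicates 1 and 2 or marker-negative replicates 1, 2 and 6, each in turn (2.34 to 2.78).

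Lists of stem cell factors and of the cell cycle did not pass the camera test. None of 13 stem cell and self-renewal genes passed, with Klf4 at 1.33 (SE 0.39, adjusted p = 0.0962), a median of -0.03, a mean of 0.32 and an upward test direction (camera adjusted p = 0.845). On marker-positive replicates 1 to 3 the mean log2 ratio of the stem cell list was 1.01, 1.44 and 0.22. On marker-negative arrays it ran from 0.30 to 0.94, so replicates 1 and 2 lay above that range and replicate 3 below it. Within slides 1 and 2 its median differences were -0.18 and 0.89. None of 16 cell cycle genes passed, with Cdc20 at -1.48 (SE 0.48, adjusted p = 0.130) and a median of -0.21 (adjusted p = 0.372). Of 15 Wnt pathway genes the receptor Fzd1 was higher (2.48, SE 0.55) and the target gene Sp5 lower (-2.94, SE 0.39), with 2 higher and 1 lower adjusted over the list alone and a median of 0.67 (adjusted p = 0.104). Bmp7 was lower (-1.92, SE 0.43) among 16 TGF-beta and BMP genes, with 1 higher and 1 lower adjusted over the list alone and a median of 0.56 (adjusted p = 0.0683). None passed over all genes among 8 Hedgehog genes (median 0.21, adjusted p = 0.165, 2 higher adjusted over the list alone), 13 glycolysis genes (0.25, adjusted p = 0.157, 1 higher adjusted over the list alone) and 16 ribosomal protein genes (-0.27, adjusted p = 0.102). The same held for 15 oxidative phosphorylation genes (-0.02, adjusted p = 0.486), 8 neuroendocrine genes (-0.51, adjusted p = 0.263) and 8 Schwann cell genes (-0.09, adjusted p = 0.912), and adjusted over the list alone 0 genes passed in these 3 lists and in the stem cell, cell cycle and ribosomal lists. On marker-positive replicates 1 to 3 the mean log2 ratio of the Wnt list was 0.38, 0.66 and -0.68. That of the TGF-beta and BMP list was 0.85, 0.90 and -0.28, and that of the Hedgehog list -0.06, 0.15 and -0.67. Marker-negative arrays ran from -0.92 to -0.05, -0.36 to 0.32 and -0.97 to -0.35. Replicates 1 and 2 lay above these ranges and replicate 3 within them. Fzd1 (3.07), Sp5 (-2.71) and Bmp7 (-1.77) did not pass when slide was a fixed block. Of the called genes named from lists and not among the 24 largest differences, Ly6c1 (5.07), Tpsb2 (2.37), Alas2 (-2.98) and Ier3 (3.73) did pass then. The others did not, among them Vwf (3.88), Oasl2 (2.48), Usp18 (2.08), Lyz2 (5.57), Hba-a1 (-3.02), Vim (3.03) and Ccl7 (5.28). Median centring ended the calls of Fzd1 (2.68) and Bmp7 (-1.81), as did no detection filter, processed signals that of Fzd1 (3.02), and the mean of a gene's probes that of Bmp7 (-1.62). The Fzd1 call ended without marker-positive replicates 1 and 2 or marker-negative replicates 1, 2, 3 and 6, each in turn (2.31 to 2.60), and the Bmp7 call without any array but marker-negative replicate 4 (-2.20 to -1.68).

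The authors' deposited table listed 2419 of 43379 rows at an adjusted p under 0.05, with 1064 higher and 1355 lower in stem cells by its fold column. In every row of the authors' deposited table the log2 column has the opposite sign to that fold column, so directions were taken from the fold column. Across 28332 probes the log2 differences of the authors' deposited table, with the sign turned, correlated with those fitted here at 0.9997, and genes are not independent replicates. The authors' deposited table gave F13a1 as 251-fold higher, Ccl24 as 90.6-fold higher and Ly6a as 14.7-fold higher in stem cells. Prom1 had a signed fold of -1.37 in the authors' deposited table (adjusted p = 0.784) and Gzma one of -99.1 (adjusted p = 0.000192).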

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

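The tests on the leukocyte lists and on stromal RNA in marker-positive replicate 3 were chosen after the result was seen, while the test of Cy5 signal in that replicate was chosen before.

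Among the 6 marker-negative arrays, 7 of 60 groups of values held an array far from the others, where chance gives about 1 in 20. Replicate 3 stood at a log2 ratio of 5.29 for the mast cell gene Cpa3 against -0.25 to 0.33 on the others, at 2.97 for the mean of the mast cell list against 0.64 to 1.24, and at 5.63 for the mean of the erythroid list against 3.66 to 4.35. Replicate 4 stood at 3.92 for Ear1 against -0.13 to 0.97 and at 3.05 for Rnase2a against 0.21 to 1.20, both genes of eosinophils. Replicate 2 stood at 2.94 for Ctsw, a protease of cytotoxic lymphocytes, against 5.05 to 6.26. Replicate 1 stood at 0.58 for Cd163 against -0.19 to 0.05, where no marker-negative array was well above background.

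Of macrophage genes 3 of 12 and of mast cell genes 3 of 9 were higher and of lymphocyte genes 4 of 12 lower in marker-positive cells, while the list calls ended with an estimated correlation (adjusted p = 0.414, 0.306 and 0.414). A larger share of all leukocytes in that fraction would move these lists alike, but their medians were 1.02, 2.49 and -1.67. The lymphocyte median lay 3.15 below that of the pooled macrophage and mast cell lists (difference -3.15, two-sided permutation test over genes, p = 2e-05). That p-value restates the pattern that prompted the test, and genes are not independent, so it adds no support. Leukocyte RNA may have been present in both fractions, since 10 of 10 genes shared by all leukocytes were well above background on all 9 arrays. Their Cy5 percentiles among probes, which differ in affinity and so give no share of RNA, ran from 74.5 (Vav1) to 99.4 (Cd52) in marker-positive and from 66.1 (Cd53) to 98.7 (Cd52) in marker-negative cells. Whether the lineage-negative gate removed such cells cannot be told, since the labels do not list its antibodies. Expression of these genes by prostate cells or a sort of leukocytes by CD44, Sca-1 or CD117 stays open and untested.

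Marker-positive replicate 3 correlated with replicates 1 and 2 at 0.609 and 0.582, below every marker-negative pair. It had the lowest share of probes above background. It correlated more with marker-negative replicates 4 (0.677) and 6 (0.676), and at 0.483 to 0.589 with the other marker-negative arrays. Marker-positive replicates 1 and 2 also correlated more with marker-negative replicate 1 (0.721 and 0.729) than with marker-positive replicate 3. Probes lost to background in Cy5 on that array would be removed by keeping probes detected on all arrays. Yet over 15294 probes detected in both channels on all arrays, the highest correlation of replicate 3 with marker-positive replicates 1 and 2 was 0.692. That lay below the lowest marker-negative pair (0.737), while marker-positive replicates 1 and 2 correlated at 0.943. The filter does not remove noise or compressed ratios among the probes kept, so lower signal quality is not excluded. The slope of observed on expected spike-in log ratios was 0.649 on replicate 3, against 0.825 and 0.820 on marker-positive replicates 1 and 2. On marker-negative arrays that slope ran from 0.638 to 0.883. Less stromal and endothelial RNA in that replicate may be part of the pattern, as 28 of 29 fibroblast and endothelial genes were lower there than in both other replicates, with a median difference of 3.09 against 0.88 between replicates 1 and 2. The fall was not limited to these lists. On marker-positive replicates 1 to 3 the luminal list mean was 2.31, 2.43 and 0.32, and the basal one 1.88, 2.44 and 0.19. The all-leukocyte mean (1.81, 0.98 and 2.59) and the lymphocyte mean (-0.40, -0.55 and 1.02) were highest on replicate 3. A difference between animals or sorts stays open and untested, since the labels describe neither. Replicate 3 was also the only array on slide 5, so an effect of that slide cannot be told apart from a difference of the sample.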

How the results depend on the processing

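The analysis of slides 1 and 2 alone and the model with Cy5 detection as a covariate were chosen after seeing the data. Of the 84 splits of the 9 arrays into 3 and 6, 1, the real split, gave as many called genes (643). The highest of the others gave 21. The splits treat the arrays as exchangeable, across slides and despite the correlation of 0.923 between marker-positive replicates 1 and 2. They therefore do not exclude chance, and they say nothing of animals or sorts, which the labels do not give. With median centring within arrays 141 genes were higher and 85 lower. With slide as a fixed block they were 125 and 20, 8 of the 24 named genes, 1 sort marker and Prom1 at 0.0200; slides 3 to 5 then add nothing to the difference. With array weights, where marker-positive replicate 3 had a weight of 0.240, they were 2211 and 2260, with Prom1 at 0.11. Cy5 detection as a covariate gave 510 and 522, and a fold of at least 2 as a tested threshold gave 40 and 29. On slides 1 and 2 only, 184 genes were lower and 13 named genes passed. Detection in both channels on all arrays left 8 named genes to test, and all 8 passed. Of 19 called lists 0 held with an estimated correlation (camera) and 4 held with fry's directional test (secretory, mast cell, erythroid and interferon genes). Of all 30 lists 13 passed fry's mixed test. Among them were the Wnt (fry mixed adjusted p = 1.49e-05) and Hedgehog (fry mixed adjusted p = 0.0130) lists, which camera did not call. Leaving out single arrays gave 98 to 933 higher and 87 to 498 lower genes, 0 to 3 sort markers, and Prom1 at -0.97 to 0.38, positive only without marker-positive replicate 3, while processed signals gave Prom1 at -1.76. Except where the construction shows it, the cause was not tested. The other settings kept each of these counts within 1.5 times. All 53 called genes followed in the text kept their sign without each array and with the slide block. The groups did not overlap in 639 of the 643 called genes. A gene without overlap cannot change sign in these settings, so the kept signs add no support. Of the 53 gene calls, 29 were kept without each array and 13 with the block. Of 19 list calls 9 and 17 were kept. Adjusted p over all alternatives ran from 4.61e-06 to 0.0246 for Cd163 and from 0.00271 to 0.130 for Kit. Array signal over background limits the weakest genes: 15 called genes were not well above background on any marker-negative array and 7 on any marker-positive array. The authors' values as an alternative, and lists with slide as a random block, were not run.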

Other observations

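The gene families and the histone genes described here were chosen after their values were seen, as were the comparison with the cell cycle list and the probe examples, while the test of partner probes was chosen before its result was seen.

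All 5 measured eosinophil-associated ribonuclease genes were higher in marker-positive cells, with Ear10 at 4.46 (SE 0.68, limma adjusted p = 0.00957). Ear2 (3.55, SE 0.66) and Ear6 (3.21, SE 0.63) were not well above background on any marker-negative array, so these values are set against background. Ear10 was well above background on 1 marker-negative array. Of 7 interferon-induced transmembrane genes 4 were higher, Ifitm3 (3.36, SE 0.38), Ifitm7 (3.32, SE 0.33), Ifitm2 (1.81, SE 0.23) and Ifitm6 (5.17, SE 0.95). Of 17 CC chemokines 4 were higher, among them Ccl9 (3.40, SE 0.70), while the family median was -0.02 and turned positive with median centring (0.01), with Cy5 alone (0.03) and with a block for slide (0.69). Higher too were, of 12 CXC chemokines, Cxcl9 (4.06, SE 0.46) and Cxcl14 (2.08, SE 0.46). The complement genes Cfp (3.93, SE 0.35) and Cfb (3.92, SE 0.44) were higher and C1s2 (-4.14, SE 0.51) lower among 14 measured. Ifng, the interferon of T and NK cells, was lower (-4.19, SE 0.73), as were the anion transporters Slc26a4 (-4.30, SE 0.71) and Slc26a3 (-2.77, SE 0.57). Ifng was well above background on 1 marker-positive array. Every gene named here kept its direction with processed signals, median centring, quantile scaling and Cy5 alone, and with a block for slide. With the block, a kept direction follows for genes whose groups do not overlap. Ear6, Ifitm3, Ifitm7, Cxcl9 and Cfb still passed with the block and the others did not.

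Some replication-dependent histone genes were lower in marker-positive cells. Of 27 tested 16 were lower and 0 higher, with a median of -2.41, differences from -4.53 to -0.25, medians of -1.99 and -2.39 within slides 1 and 2, and a negative sign for all 27 under each scaling. H4c6 (-4.34, SE 0.41, adjusted p = 0.00110), H3c1 (-3.47, SE 0.51) and H2ac18 (-2.41, SE 0.49) were among them, and many of these genes are near-identical copies. A fixed block for slide kept 5 of the 16 calls (H4c1, H4c4, H4c6, H4c14 and H2ac20). All 16 kept their sign, which follows for genes whose groups do not overlap.

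If fewer cycling cells in the marker-positive fraction lowered both alike, the cell cycle list would fall by about as much as the histone genes. Its median lay 2.21 above that of the histone genes, and its lowest gene, Cdc20 (-1.48), also lay above the histone median. That both would fall alike was assumed and not tested, so the comparison does not exclude fewer cycling cells. Most histone transcripts lack a poly(A) tail, so amplification of more unspliced or unpolyadenylated RNA from marker-negative cells is a candidate explanation. It would leave probes called lower with an unmoved partner probe of the same gene more often than probes called higher, which held for 166 of 364 (45.6%) against 81 of 214 (37.9%), an odds ratio of 1.38 (95% interval 0.962 to 1.97, Fisher's exact p = 0.0815). That interval includes 1, so this explanation cannot be told apart from a change in the histone genes themselves. A difference between the sorted cells stays open and untested.

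Probes of the same gene disagreed in several genes, with U2af2 at -4.01 and -0.26, Nop53 at -3.74 and -0.44 and Calr at -3.30 and -0.90.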
